A study of Mus musculus with 10 samples.

How the data were processed

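Bone marrow was flushed from 1 hindlimb of each of 5 male and 5 female C57/BL6 mice, an inbred laboratory strain, at steady state. Cells that carried markers of mature blood lineages were removed with magnetic beads, which left a preparation enriched for hematopoietic stem and progenitor cells (HSPC). Total RNA was extracted from these cells and sequenced in bulk, with 1 library per mouse, so the n of 5 per sex counts separate animals. Libraries were made by a commercial provider, per the labels. The kit, the strand setting of the counting and the antibodies of the depletion are not given in the sources used here.

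The submitters' processing notes name STAR, featureCounts and DESeq with the builds GRCm38.p6 and mm10, without versions. The authors deposited a table of raw read counts per Ensembl gene for the 10 libraries, and a table of normalized values (signal). In each library the deposited normalized values equalled the raw count divided by 1 size factor, which ran from 0.852 in male replicate 2 to 1.13 in female replicate 5. The count table held 25178 genes, of which 25116 were found by identifier in GENCODE vM21 (GRCm38), and symbols, chromosomes and coordinates come from that release. The other 62 genes have no symbol or chromosome from it. The annotation release behind the deposited counts is not given in the sources used here. Counts summed to between 20754101 (female replicate 1) and 24759687 (male replicate 1) per library. Intervals and floors computed from counts cover counting error only, since PCR copies were not told apart.

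The comparison, the gene lists, the rule for named genes and all alternatives except the 2 named at the end were fixed before the data were examined. Genes were filtered with edgeR's filterByExpr by sex, which kept 14674, and scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 (robust glmQLFit and glmQLFTest, R 4.3.3) was fitted with sex as the only term, and log2 fold changes are given as female against male. The SE of a fold change was taken as its size divided by the square root of the F statistic. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to the library's total over the genes kept times its TMM factor, with the SD over 5 mice.

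Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, adjusted over 34 lists. The cell type lists covered stem cells, multipotent progenitors, lymphoid-primed progenitors, megakaryocytes and platelets, erythroid cells, primary and mature neutrophil granules, monocytes, macrophages, dendritic cells, B lineage, plasma cells, T and natural killer cells, mast cells with basophils and eosinophils, stroma and endothelium. The pathway lists covered heme synthesis, adhesion and homing, growth factor receptors, prostaglandins, steroid receptors, S phase, mitosis, quiescence, interferon, inflammation, MHC class II, p53, TGF-beta and BMP, oxidative phosphorylation and glycolysis. Immediate early, mitochondrially encoded and ribosomal protein genes served as signs of RNA or handling quality. Y-linked genes and X-linked genes that escape inactivation served as a check of the labels. Each list was also tested by camera with an estimated correlation, by fry, and by an exact two-sided permutation of the list's mean log2 CPM per mouse over all 252 assignments of 5 of the 10 mice, whose smallest possible p is 0.00794. Camera compares a list with the other genes, fry tests whether the genes of a list moved on balance one way, and the permutation treats the mouse as the unit.

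The genes named are all measured genes of the Y-linked and X-escape lists. Outside the X and Y chromosomes, the rule took up to 12 called genes per direction with a mean of at least 1 CPM, without predicted genes and antigen receptor segments, filled up with the uncalled genes of smallest p to 5 per direction. It further took up to 4 members of smallest p from each list with a called result or a called member, and a few genes fixed by name, of which Hpgd, Esr1 and Cxcr4 are given, called or not. Some genes that the rule takes are not reported here and were left out of the search for single mice that stand apart. Where another gene is named, it was chosen after its values were seen.

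The procedure was tested on simulated counts for this comparison, drawn with the means, library sizes and group sizes of the real data. After filtering, 14502 simulated genes were fitted. Of 100 genes changed by 1 on the log2 scale 78% were recovered, and of 100 changed by 2, 100% were recovered. Of the 187 genes called in the simulation, 6 were unchanged genes. In the real data 8 genes were called. The adjustment is stricter when fewer genes change, so the recovery in the simulation need not hold for the real comparison. A list whose members were raised by 0.4 was called and 0 other lists were. The simulated genes varied independently, so this does not show how often lists of correlated genes are called by chance. In the real data the estimated correlation between genes was 0.163 in the megakaryocyte list and 0.94 in the ribosomal protein list.

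The alternatives were other filters on low counts, DESeq2 size factors, upper-quartile and total-count scaling, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, limma-trend on log2 of the deposited normalized value plus 1, the replicate number as a block, 1 surrogate variable (sva 3.50.0), removal of hemoglobin, immunoglobulin and mitochondrial genes, a stricter threshold, and leaving out each library. After the data were seen, a fit without male replicates 1 and 2 and a correction of each library for transcript length and GC content were added.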

Results

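The data set holds RNA-seq counts from lineage-depleted bone marrow of 5 female and 5 male mice and addresses how hematopoiesis differs between the sexes without injury. Total counts per library averaged 22637200 ± 1513990 (SD, n = 5) in females and 23133900 ± 1644680 (SD, n = 5) in males. The difference was smaller than the spread between mice (exact two-sided permutation p = 0.611, adjusted p = 0.651 over 8 library measures). Replicate libraries of a sex correlated across genes with r between 0.948 and 0.990, and every pair differed by more than sampling noise (chi-square per degree of freedom at least 8.98). Male replicates 1 and 2 stood apart from the other libraries on the first principal component (scores 35.3 and 36.6, the others at most 6.04), which held 38.4% of the variance of the 1000 most variable genes. Male replicate 2 had the lowest TMM factor (0.886, against 0.964 to 1.05 in the others), and its deviations from the mean fell with transcript length (rank correlation across genes -0.552).

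The sex-linked genes separated the mice as labelled. Xist, the RNA that coats the inactive X chromosome (X: 103460366 to 103483254), was at 42.0 ± 7.45 CPM in females and 0.0772 ± 0.0802 CPM in males (SD, n = 5 each). Its log2 fold change was 9.10 (SE 0.32, adjusted p = 1.73e-08). The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d averaged 61.3, 31.6, 18.2 and 17.1 CPM in males. No count of Ddx3y or Uty was found in females, so that, with a floor of 3 counts over the 5 females, they were at least 1232-fold and 717-fold lower. For Eif2s3y 2 counts were found in females, a male to female ratio of 3524 (95% counting interval 975 to 29100), and for Kdm5d 1 count, a ratio of 2024 (363 to 79970). The Y-linked predicted gene Gm29650, outside the rule for named genes, had 102 counts in males and 0 in females, at least 35.0-fold lower (adjusted p = 0.0400). Usp9y and Zfy1 were not analysed here.

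Of the X-linked genes known to escape inactivation, Eif2s3x, a subunit of translation initiation factor 2 (X: 94188707 to 94212862), was higher in females at 490 ± 20.4 CPM against 315 ± 31.4 CPM (log2 fold change 0.64, SE 0.09, adjusted p = 0.0176). The histone demethylase genes Kdm6a and Kdm5c did not pass the adjusted test, although all 5 females lay above all 5 males for both. Kdm6a was at 57.0 ± 4.28 CPM in females and 30.1 ± 7.91 CPM in males (adjusted p = 0.193), and Kdm5c at 203 ± 16.9 and 115 ± 41.8 CPM (adjusted p = 0.506). Ddx3x (log2 fold change 0.14), 5530601H04Rik (0.12), Jpx (0.03), Pbdc1 (0.00) and Ftx (-0.17) had values within 2 SE of 0 in the edgeR fit. Of 533 X-linked genes tested, 2 were called, Xist and Eif2s3x. The mean log2 CPM of X-linked minus autosomal genes differed between the sexes by 0.0112 (exact permutation p = 0.587, adjusted p = 0.651). Leaving out any of 8 libraries other than male replicates 2 and 4 ended the call of Eif2s3x (adjusted p between 0.0514 and 0.0941). Its log2 fold change lay between 0.58 and 0.67 in all 10 of these fits. The paralogs Eif2s3x and Eif2s3y can share reads. The 5 females had 56949 counts of Eif2s3x and 2 of Eif2s3y, so few reads of Eif2s3x were counted as Eif2s3y. Whether reads of Eif2s3y were counted as Eif2s3x in males cannot be read from these values. The strand setting of the counting is not given in the sources used here. The levels of Xist and its antisense partner Tsix (16 counts over the 10 libraries) are uncertain to that extent.

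**Figure D1:**
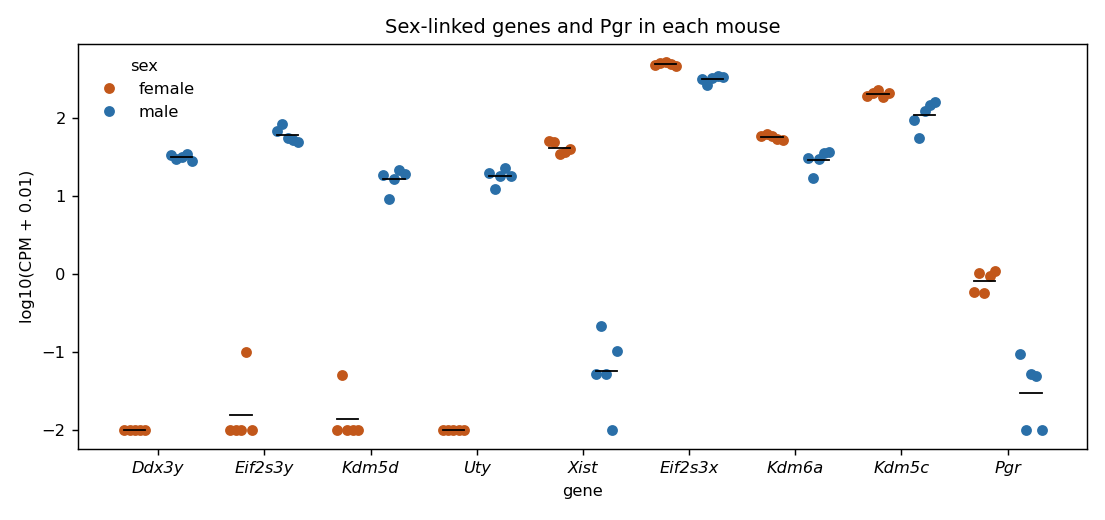
Level of sex-linked genes and of Pgr in each mouse, as log10 of CPM plus 0.01 on the vertical axis. Each point is 1 mouse (orange female, blue male, n = 5 each), the horizontal line is the mean of the plotted values, and a point at -2 had 0 counts. For Xist, Eif2s3x, Kdm6a, Kdm5c and Pgr all 5 females lie above all 5 males, and for the Y-linked genes all 5 lie below.

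Outside the sex chromosomes, females had more transcripts of Pgr, the progesterone receptor gene (chromosome 9: 8899833 to 8968611), than males. It had 99 counts over the 5 females and 4 over the 5 males, that is 0.840 ± 0.254 CPM against 0.0333 ± 0.0350 CPM (SD, n = 5 each). The ratio of its counts per TMM-scaled total was 24.0 (95% counting interval 9.09 to 89.9). Single females had between 12 and 28 counts of Pgr and single males between 0 and 2. Pgr was the only one of 14131 genes outside X and Y that was called (log2 fold change 4.38, SE 0.52, edgeR adjusted p = 0.00559). No gene there was called lower in females. At an unadjusted p under 0.05, 523 of these genes were higher and 755 lower in females, against 707 of either direction expected by chance. Over all genes tested, this count was 1346 (734 expected) and depended on single libraries. It was 790 without female replicate 2 and 854 without female replicate 3, and 2227 and 2284 without male replicates 4 and 5. The Wald test of DESeq2 called 32 higher and 11 lower, including Pgr. A filter that asks for 1 CPM in at least 5 libraries removed Pgr, which left 0 calls outside X and Y in that fit. Over all 14674 genes 8 were called, 3 higher and 5 lower in females. There were 12 calls without male replicates 1 and 2, an alternative chosen after seeing the data.

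The uncalled genes with the smallest p that were higher in females were Pls1, an actin-bundling protein (log2 fold change 0.71, SE 0.12, adjusted p = 0.105), Plekha8 (0.58), the chaperone Hsph1 (0.56), the hypoxia-inducible factor gene Epas1 (1.66, SE 0.30, adjusted p = 0.170) and the platelet glycoprotein gene Gp5 (0.45). All 5 females lay above all 5 males in each of these 5 genes. Those lower in females were the 4 adult hemoglobin genes and Apol11b (log2 fold change -2.16, SE 0.44, adjusted p = 0.204), with all 5 females below all 5 males. Hpgd, Esr1 and Cxcr4, fixed beforehand as genes of interest, had no call. Hpgd, the enzyme that degrades prostaglandin E2, was at 2.18 ± 0.303 CPM in females and 3.51 ± 2.58 CPM in males (adjusted p = 0.508). The estrogen receptor gene Esr1 was at 3.38 ± 0.836 and 4.33 ± 0.412 CPM in females and males, and the homing receptor gene Cxcr4 at 64.6 ± 1.77 and 75.8 ± 11.8 CPM. Both had an edgeR adjusted p of 0.506.

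Megakaryocyte and platelet genes were higher in females. All 16 measured members had a positive fold change, with a median log2 value of 0.45, and the list rose against other genes (camera adjusted p = 4.68e-09, but 0.201 with an estimated correlation). Of its members 8 were higher at an adjusted p under 0.05 when adjusted over the list alone, and 0 when adjusted over all genes tested, while DESeq2 called Gp5, Itga2b and Itgb3. The fibrinogen receptor subunits Itga2b and Itgb3 were at 420 ± 45.3 and 344 ± 64.2 CPM in females and 301 ± 37.0 and 215 ± 48.0 CPM in males (SD, n = 5 each). Gp5 was at 133 ± 11.2 against 97.6 ± 6.31 CPM, and the collagen receptor gene Gp6 at 23.1 ± 4.53 against 15.1 ± 3.28 CPM. Per mouse, the mean log2 CPM of the list was 6.51 ± 0.177 in females and 6.04 ± 0.0499 in males. Every female lay above every male (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0900 over the 34 lists). Only fry of the 3 other list tests called the list (adjusted p = 0.0319).

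**Figure D2:**
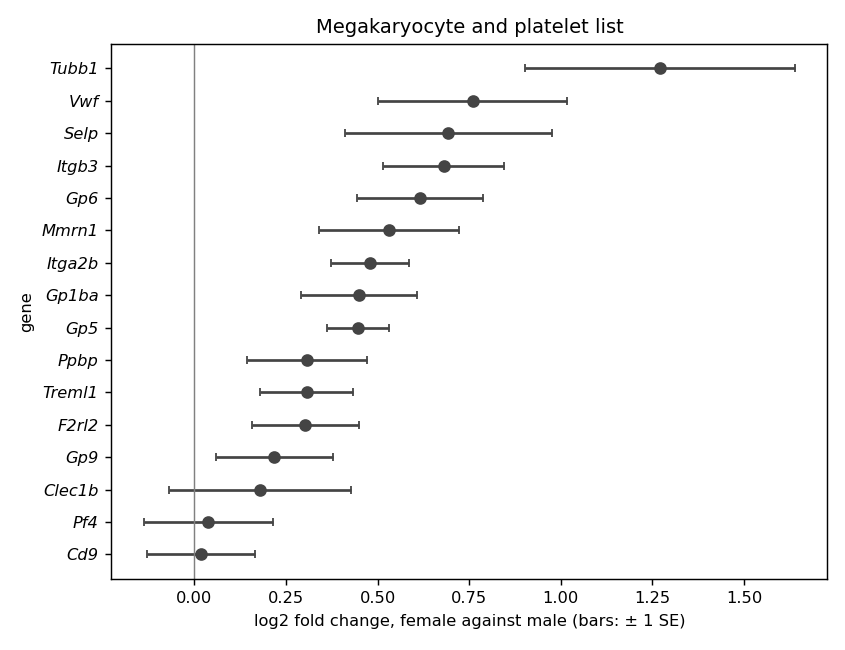
Log2 fold change of each measured megakaryocyte and platelet gene, female against male (horizontal axis, edgeR estimate), with bars of 1 SE to either side and n = 5 mice per sex. All 16 estimates lie above 0, from 0.02 for Cd9 to 1.27 for Tubb1.

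Endothelial and steroid receptor genes also rose in females by the camera test. Of 11 measured endothelial genes 10 had a positive fold change (median log2 0.52, adjusted p = 0.00242; adjusted p = 0.503 with an estimated correlation), and 0 passed when adjusted over the list alone. The leading members were Vwf, which megakaryocytes also express (318 ± 66.9 against 188 ± 78.9 CPM), and Kdr (7.36 ± 1.68 against 4.65 ± 2.01 CPM). Plvap had a log2 fold change of 0.25 and Egfl7 of -0.25. Per mouse, every female lay above every male for the whole list (exact permutation p = 0.00794, the smallest possible). The test still did not pass over the 34 lists (adjusted p = 0.0900). Without Vwf the list mean was still higher in females by 0.39 (exact permutation p = 0.00794, adjusted p = 0.0231 over 32 tests chosen after seeing the data). These 32 tests include several versions of the same effects, so their adjusted p cannot be set against that over the 34 lists. Without female replicate 4 the median of the whole list was 0.34 (camera adjusted p = 0.00755). Of 11 steroid receptor and response genes 8 had a positive value (median log2 0.28, adjusted p = 9.85e-04; adjusted p = 0.627 with an estimated correlation), and 2, Pgr and Per1, passed when adjusted over the list alone. The clock gene Per1, which glucocorticoids induce, was at 31.9 ± 3.89 against 19.4 ± 4.11 CPM. Fkbp5 was at 79.8 ± 7.40 against 63.9 ± 12.3 CPM. For this whole list too every female lay above every male (exact permutation p = 0.00794), and the test did not pass over the 34 lists either (adjusted p = 0.0900). Without Pgr the list mean was higher in females by 0.22 (exact permutation p = 0.0159, adjusted p = 0.0409 over the same 32 tests). Its unadjusted p was larger than that of the whole list, and the lower adjusted p came from the other family of tests. Without male replicates 1 and 2 the median of the whole list was 0.11 (camera adjusted p = 2.48e-04).

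Hemoglobin transcripts were less abundant in females. The genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt made up 0.567% ± 0.163 of all counts in females and 2.18% ± 1.39 in males (SD, n = 5 each). Each female lay below each male (exact permutation p = 0.00794, adjusted p = 0.0635 over 8 library measures). Their log2 fold changes ran from -2.25 for Hbb-bs to -1.87 for Hba-a1 (edgeR adjusted p = 0.193 for each), and DESeq2 called all 4 (adjusted p between 1.12e-04 and 0.00675). Reads of the near-identical copies within each pair cannot be assigned with certainty. The highest share was in male replicate 1 at 4.40%, and without that library males averaged 1.62%. The erythroid list fell by the camera test (adjusted p = 0.0269; adjusted p = 0.627 with an estimated correlation). Of its 22 members 14 were lower, with a median of -0.07, and 4, the hemoglobin genes, passed when adjusted over the list alone. The heme synthesis list fell as well (median -0.15, adjusted p = 0.0227; adjusted p = 0.627 with an estimated correlation), led by Alas2, the first enzyme of the pathway in red cells, at 39.1 ± 13.3 CPM in females and 142 ± 96.9 CPM in males. Alas2 alone passed when adjusted over the list alone, and the iron carrier Slc25a37 (-0.56) and Ppox (-0.21) did not. The camera calls of the erythroid and heme synthesis lists ended without male replicate 4 or 5 or female replicate 4 or 5 (adjusted p between 0.0779 and 0.200), and the erythroid median was between -0.16 and -0.00163 over all fits that left out 1 library. The heme synthesis median was -0.08 without male replicate 2 and -0.22 without female replicate 1.

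Genes of mature neutrophils and of the B lineage were lower on average in females, with wide variation between males. All 15 mature neutrophil genes had a negative fold change (median log2 -2.36, camera adjusted p = 6.12e-08; adjusted p = 0.627 with an estimated correlation), and 13 passed when adjusted over the list alone. The calprotectin genes S100a8 and S100a9 were at 78.3 ± 44.1 and 126 ± 78.6 CPM in females and 549 ± 664 and 810 ± 923 CPM in males. The granule gene Camp was at 34.6 ± 18.0 against 205 ± 236 CPM and Ly6g at 1.57 ± 1.06 against 13.1 ± 16.4 CPM. The estimated correlation between the genes of this list was 0.872, so the 13 that passed are not separate observations. Per mouse the list did not separate the sexes (exact permutation p = 0.0873, adjusted p = 0.371). Without male replicate 1 the list mean differed by -0.99 (exact permutation p = 0.143, chosen after seeing the data). Male replicate 5 lay 1.41 below the mean of the 10 mice, while male replicates 1 and 2 lay 2.95 and 1.12 above it. The median was -1.33 without male replicate 1 and -0.92 without male replicates 1 and 2. Of 12 B lineage genes 11 were lower (median log2 -0.96, adjusted p = 5.00e-05; adjusted p = 0.627 with an estimated correlation), and 7 passed when adjusted over the list alone, among them Pax5, Cd79a, Vpreb1 and Vpreb3. Pax5 was at 0.213 ± 0.143 CPM in females and 1.58 ± 0.906 CPM in males, and Cd79a at 1.57 ± 0.326 against 4.99 ± 3.22 CPM. The exact permutation p of the B lineage list was 0.0317 (adjusted p = 0.216), and male replicate 1 lay 1.38 above the mean. The B lineage median was -0.57 without male replicates 1 and 2, and -1.44 and -1.46 without male replicates 3 and 5. Without male replicate 1 the mean of the B lineage list differed by -0.65 (exact permutation p = 0.0556, chosen after seeing the data).

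**Figure D3:**
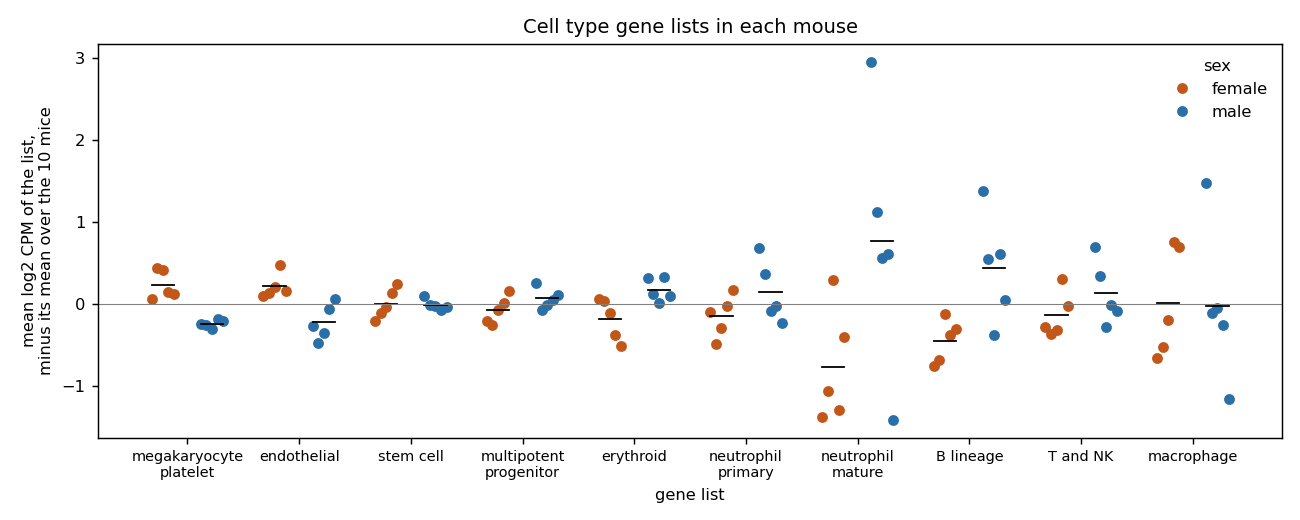
Mean log2 CPM of 10 cell type gene lists in each mouse, minus the list's mean over the 10 mice (vertical axis, log2 units). Each point is 1 mouse (orange female, blue male, n = 5 each) and the horizontal line is the mean of the sex. For megakaryocyte and platelet genes every female lies above every male, and for mature neutrophil genes male replicate 1 lies 2.95 above the mean and male replicate 5 lies 1.41 below it.

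Other lists that fell in females by camera were primary neutrophil granule genes (median log2 -0.28, adjusted p = 0.00539), MHC class II genes (-0.51, adjusted p = 4.66e-04), mast cell, basophil and eosinophil genes (-0.34, adjusted p = 0.0283) and quiescence genes (-0.17, adjusted p = 0.0483). With an estimated correlation the adjusted p was 0.627 for these 4 lists and for the next 3. Among their members the basophil protease gene Mcpt8 was at 231 ± 88.2 against 374 ± 101 CPM and the mast cell protease gene Cpa3 at 65.1 ± 18.1 against 99.6 ± 16.7 CPM. H2-Oa had a log2 fold change of -0.62, Nkg7 of -0.55 and Btg2 of -0.44. Ribosomal protein (median -0.25, adjusted p = 1.22e-06), nuclear-encoded oxidative phosphorylation (-0.20, adjusted p = 1.65e-04) and mitochondrially encoded genes (-0.23, adjusted p = 0.0205) fell in females as well. Male replicate 2, the library whose values fell most with transcript length, lay 0.728 above the mean of the 10 mice for ribosomal protein genes, whose median was -0.06 without it, as was that of oxidative phosphorylation genes. Without male replicate 1, the calls of primary granule genes (median -0.11, adjusted p = 0.0847), mast cell, basophil and eosinophil genes (-0.09, adjusted p = 0.318) and quiescence genes (-0.08, adjusted p = 0.149) ended and the MHC class II median was -0.28. The primary granule median was -0.18 without female replicate 2, and the quiescence median -0.26 without male replicate 3. The MHC class II call ended without male replicates 1 and 2 (adjusted p = 0.291). Of the 10 fits that left out 1 library, the call of mast cell, basophil and eosinophil genes ended in 4 (male replicates 1 and 4, female replicates 2 and 3). That of quiescence genes ended in 6 (male replicates 1, 4 and 5, female replicates 3, 4 and 5, adjusted p up to 0.178). The call of mitochondrially encoded genes ended in 3 (adjusted p up to 0.0924), namely without male replicate 2, where the median was -0.13, male replicate 5 and female replicate 4. Of the members of these 7 lists 0 passed when adjusted over the list alone. In total camera called 14 of 34 lists, 3 higher and 11 lower in females. With an estimated correlation 0 of them were called (2 of 34 at an unadjusted p under 0.05), fry called 1, and the exact permutation 0 (5 at an unadjusted p under 0.05).

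Stem cell, progenitor and cell cycle genes gave no call by camera, although progenitor genes did under some other settings. The stem cell list had 9 of 17 members higher and 8 lower (median log2 0.02, camera adjusted p = 0.869), and the multipotent progenitor list 10 of 15 lower (median -0.14, adjusted p = 0.0596). S phase genes (median 0.02, adjusted p = 0.938), mitosis genes (0.01, adjusted p = 0.906), growth factor receptors (-0.11, adjusted p = 0.466) and adhesion and homing genes (-0.08, adjusted p = 0.644) did not pass the test. Lymphoid-primed genes had an adjusted p of 0.112 (median -0.19), with 3 of 10 members lower when adjusted over the list alone, and T and natural killer cell genes 0.0526 (median -0.33), with 1 of 13. Interferon genes had an adjusted p of 0.0707 (median 0.15, 17 of 25 higher). Under 27 alternatives, interferon genes passed in 8 (adjusted p down to 3.58e-08), multipotent progenitor genes in 7 (down to 0.00253) and lymphoid-primed genes in 5 (down to 0.00253). T and natural killer cell genes and growth factor receptors passed in 4 each, and stem cell, S phase and mitosis genes in 0. With 1 library left out, interferon genes passed without male replicate 1 or 2 or female replicate 1 or 2, and multipotent progenitor genes without male replicate 2 or 3 or female replicate 5. Lymphoid-primed genes and growth factor receptors passed without male replicate 2, and T and natural killer cell genes without male replicate 3 or female replicate 4 or 5. Monocyte genes passed without female replicate 5 (adjusted p = 0.0188), and plasma cell (0.0440) and macrophage genes (0.0205) without male replicate 1. The remaining lists were further from the threshold with all libraries, namely monocytes (adjusted p = 0.183), inflammation (0.256), immediate early genes (0.312), glycolysis (0.356), dendritic cells (0.378), plasma cells (0.613), stroma (0.629), macrophages (0.869), prostaglandins (0.869), p53 targets (0.930) and TGF-beta and BMP signalling (0.930). In 6 uncalled lists (macrophages, prostaglandins, S phase, mitosis, p53 targets and TGF-beta and BMP signalling) the median, the mean and the test differed in sign.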

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

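The tests of carried-over platelets, of carried-over red cells, of male replicate 1 alone and of a lower share of the main cell type were chosen only after the result was seen, and the lists of other heat shock, clock, erythroid and estrogen response genes were written after the data were seen.

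Within a sex, 12 of 227 groups of 5 values held a mouse that stood apart by its gap to the nearest other mouse relative to the range, against about 11 expected when chance flags 1 in 20. Of the 12, 5 were in male replicate 2. It was high for oxidative phosphorylation genes (gap over range 0.749), ribosomal protein genes (0.736) and Ndufa4 (0.748), and low for Kdm6a (0.737) and Fkbp5 (0.864). Male replicate 1 was high for TGF-beta and BMP genes (0.863). Female replicate 1 was high in the share of counts in the 10 most abundant genes (0.788), in mitochondrially encoded genes (0.789) and in ribosomal protein genes (0.795). Female replicate 4 was high for endothelial genes (0.712) and, with 2 counts against 0 in the other females, for Eif2s3y (gap over range 1). Female replicate 2 was high for Kdm5d (gap over range 1), with 1 count.

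Other splits of the 10 libraries into 5 and 5 (100 of the 126 drawn) gave as many called genes as the real one in 1 of 100 splits, the real one itself, with 8 genes and at most 2 in any other. This comparison says nothing about chance, since 7 of the 8 genes lie on X or Y and part fully only by sex. Outside X and Y the real split called 1 gene, and 4 of 100 splits, the real one among them, called at least 1. This share was under the 0.05 set beforehand. Another split called 2 genes, more than the real one, so chance cannot be excluded for a count of 1. For the gene lists 32 of 100 splits called at least 14, and another split called 25, so chance cannot be excluded for the number of lists. Every split keeps at least 3 of the 5 mice of a sex together, so part of these calls can come from sex. Of the 78 splits that keep 3 together, the nearest to balance, 23 called at least 14 lists. Whether a structure of the samples besides sex or the preset correlation between genes gave these calls was not tested. The megakaryocyte list was called in 47 of 100 splits, namely the real one, 20 of 21 that keep 4 of a sex together and 26 of the 78. Its camera p was as small as the real one in 3 of 100, the real split and 2 that keep 4 together.

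Megakaryocyte and platelet genes were higher in each female than in any male. Trends with transcript length and GC content between libraries are argued against as the whole cause, since the list difference after correcting for them was 0.482 on the log2 scale, against 0.473 before (exact permutation p = 0.00794 for both). Platelets carried over with the cells remain open, a source that depletion of mature lineages could leave. The other list members exceeded 6 transcripts abundant in platelets by 0.1398 (exact permutation p = 0.540), and the log2 fold changes of the 6 went both ways, with Tubb1 at 1.27, Ppbp at 0.31, Nrgn at 0.28, Clec1b at 0.18, Pf4 at 0.04 (SE 0.18) and Rgs18 at -0.19. Of the 6, 4 are also in the fixed lists. A difference in megakaryocyte progenitors between the sexes is a candidate explanation that these data do not test.

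Hemoglobin transcripts were lower in every female than in any male. Male replicate 1 alone is argued against as the cause, because the other males, at 0.939% or more, still lay above the highest female at 0.779%, a gap of 0.160 that follows from the separation of the sexes and is no further test of it. A lower share of the main cell type in males, which would move other types alike, stays open. Hemoglobin genes fell by 1.587 more than T and natural killer cell genes on the log2 scale (exact permutation p = 0.00794). This test cannot decide it, since the hemoglobin genes were already seen to be lower in every female. The T and natural killer cell genes alone differed by -0.27 (exact permutation p = 0.230), at a low mean log2 CPM of 0.255 in females and 0.525 in males. Reticulocytes and red cells carried over into male libraries are a candidate explanation that passed its test, although the depletion of mature lineages is meant to remove such cells. Here 16 late erythroid genes other than the adult hemoglobins, 6 of them in the fixed lists, differed from 10 early ones by -0.542 (exact permutation p = 0.00794, adjusted p = 0.0231 over 32 tests). Without the minor hemoglobin gene Hbq1b the difference was -0.513 (exact permutation p = 0.00794), while early genes such as Gata1 (log2 fold change -0.01) and Klf1 (0.05) had values near 0. A difference between the sexes in late erythroid cells of the marrow would give the same values and stays open. For mature neutrophil genes a lower share of the main cell type stays open. They moved apart from megakaryocyte genes by -2.01 (exact permutation p = 0.0238). That comparison cannot decide it, since the megakaryocyte list was already seen to be higher in every female. Against T and natural killer cell genes the difference was -1.27 (exact permutation p = 0.103).

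Hsph1 and Per1 were higher and the cold-inducible gene Cirbp was lower in females (17.6 ± 3.17 against 30.6 ± 8.89 CPM, edgeR adjusted p = 0.379), genes that follow temperature and the time of day. A temperature response is a candidate explanation that passed its test only before adjustment. The mean of 17 other heat shock genes minus the cold-inducible gene Rbm3 differed by 0.648 on the log2 scale (exact permutation p = 0.0397, adjusted p = 0.0669 over 32 tests). Most of that lay in Rbm3 (-0.52), and the heat shock genes alone differed by 0.124 (exact permutation p = 0.159), so a rise of heat shock genes was not shown. For a different time of collection the evening minus morning clock genes differed by 0.227 (exact permutation p = 0.214), which leaves it open, since the labels give no times. Handling of the samples and body temperature of the sexes both stay open, since the labels record neither.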

How the results depend on the processing

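The fit without male replicates 1 and 2 and the correction for length and GC content were chosen only after the data were seen. Over 8 called genes and 24 alternatives at most, no gene reversed, and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were called in all 24. Pgr was called in 22 of 23 fits that tested it (adjusted p 4.97e-05 to 0.310), Eif2s3x in 14 of 24 and Gm29650 in 12 of 23. No scaling moved the median of all genes by more than 0.0754.

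The genes called, in all, outside X and Y and on X, were 8, 1 and 2, against 53, 43 and 5 with the DESeq2 Wald test, 17, 8 and 4 with limma-voom weights, and 13, 4 and 4 with 1 surrogate variable. The filter at 1 CPM left 0 outside X and Y. Without male replicates 1 and 2, 3 were called outside X and Y (Pgr, Clu and Epas1) and 4 on X, and with the length and GC correction 2 outside X and Y. At an adjusted p under 0.01, 1 X-linked gene and 9 lists were called. Leaving out 1 library at a time gave 6 to 10 genes in all, 1 to 2 outside X and Y (Pax5 besides Pgr without male replicate 3, Lonrf2 without male replicate 4), 1 to 4 on X (4 without male replicate 2) and 10 to 17 lists. Lists called fell from 14 to 0 with an estimated correlation, 1 with fry and 0 with the exact permutation. By the exact permutation the megakaryocyte, endothelial and steroid receptor lists reached the smallest possible p, 0.00794, and still had an adjusted p of 0.0900. The cause of the differences between settings was not tested.

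The replicate numbers occur in both sexes, and the labels do not say whether they pair the mice. Deviations of same-numbered mice correlated at between -0.305 and -0.00724 across genes, and no mouse correlated best with its own number. These values gave no sign of pairing but cannot exclude it. With the replicate block 5 genes were called, 0 outside X and Y and 1 on X.

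Some list medians reversed in sign: ribosomal protein genes with 1 surrogate variable (0.0225), macrophages without male replicate 1 (0.38, with -0.52 to 0.38 over all libraries left out) and without male replicates 1 and 2 (0.56), mast cell, basophil and eosinophil genes without both (0.11), and erythroid (0.0197) and mitochondrially encoded genes (0.0434) with the length and GC correction. The cause was not tested. The megakaryocyte list was called in 25 of 27 alternatives, with a positive median in all. It was not called by camera with an estimated correlation (adjusted p = 0.201) or by the exact permutation (adjusted p = 0.0900). The other alternatives except fry kept the preset correlation of 0.01, below the 0.163 estimated for this list, so they do not test that setting.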

Other observations

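The prediction for estrogen response genes was set before their list was tested. The list itself was written after the data were seen, and 2 of its genes are also in the fixed lists. The genes of the next paragraph were chosen after their values were seen.

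The DESeq2 Wald test called more genes than edgeR, and some of them are given here. Thbs1, which encodes the platelet and matrix protein thrombospondin, was at 176 ± 50.9 CPM in females and 85.9 ± 24.9 CPM in males (log2 fold change 1.03, DESeq2 adjusted p = 0.0118). The collagen VI genes Col6a1 and Col6a2 had log2 fold changes of 1.27 and 1.04 (DESeq2 adjusted p = 0.0222 and 0.0342), the parvin gene Parvb 0.39 (7.33e-05) and the Hippo pathway effector Yap1 1.09 (0.0215). Aldh1a2, which makes retinoic acid, had a log2 fold change of 2.38 (DESeq2 adjusted p = 0.0126). On the X chromosome the same test called Kdm6a and Gpc4 higher and Alas2 lower, besides Xist and Eif2s3x. Among genes lower in females were the 4 adult hemoglobin genes, Bpgm, the red cell enzyme that makes 2,3-bisphosphoglycerate (-1.34, DESeq2 adjusted p = 0.0108), Pax5 and Cd79a. All 43 genes outside X and Y that DESeq2 called had the same sign in the edgeR fit, in which only Pgr was called. Both tools fitted the same counts, so the shared sign is no further support for these calls.

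Pgr is a known target of the estrogen receptor, so higher estrogen signalling in females is a candidate explanation for its level. The mean log2 CPM of 12 other genes often raised by estrogen in reproductive tissue differed by 0.0642 (exact permutation p = 0.611), which does not decide it, since these genes may not respond in marrow cells. Among them Myc had a log2 fold change of 0.27 and Igfbp4 of -0.29, neither of them called.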
